A study of Rattus norvegicus with 8 samples.

How the data were processed

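Total RNA from microdissected supraoptic nuclei of male Sprague Dawley rats aged 10 to 12 weeks was measured on 8 clone arrays, 4 hybridised with control RNA and 4 with RNA from rats dehydrated for 3 days. Per the labels' protocols, the RNA was copied into cDNA with reverse transcriptase and an oligo(dT) primer in the presence of a radioactively labelled nucleotide, so each array carries 1 sample and no second colour. The series title names suppression subtractive hybridisation (SSH), a PCR method that enriches cDNAs more abundant in one RNA population than in another. The numbers of animals or pools behind the arrays, the image quantification, the background subtraction and any scaling are not given in the sources used here.

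The values deposited by the authors are linear intensities for 1152 clones, with 1 empty cell (a c clone on control replicate 3). The values themselves show no scaling between arrays: the array medians run from 2066 to 4281, and the lowest value of an array from 752 to 1143. Of the 9215 values, 4540 have 3 decimals, and all 4540 end in 5, as the mean of 2 readings with 2 decimals each would. An unsubtracted background would make fold changes, small or large, of clones that are dim in either group smaller than they are. Arrays have no read depth, and the number of arrays limits the precision.

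Groups were taken from the sample descriptions. Replicates were numbered in accession order, which pairs nothing. The sample titles also hold a number, and these numbers form 2 runs, 3 to 6 and 16 to 19, each with 2 control and 2 dehydrated arrays. The labels do not say what a run is. Arrays with adjacent title numbers in a group (3 and 4, 5 and 6, 16 and 17, 18 and 19) were checked against each other. They agree more closely than arrays of the group from the other run, and the labels do not say whether they come from separate animals. P-values from all 8 arrays rest on the spread between arrays of a group, which holds the difference between runs and that between adjacent arrays. The latter may be technical, so the spread between animals may not be measured. The deviations of the arrays from their group means correlated across groups at 0.60 to 0.68 within a run and at -0.67 to -0.60 between runs.

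The test was written before the data were examined: quantile normalization of the 8 arrays, log2, and limma 3.58.1 in R 4.3.3 (lmFit and eBayes, control and dehydrated as the only term, two-sided) with Benjamini-Hochberg adjustment over 1152 clones and a threshold of 0.05. All intensities were above 0, so no floor or pseudocount was used in this fit. Single values per array were compared with an exact two-sided permutation test over the 70 orderings of the 8 arrays, whose smallest p is 0.0286. No clone number is paired with a gene in the sources used here, and the RefSeq gene table holds no such identifier. The tests per gene and the 20 gene lists, cell type markers included, that were fixed beforehand could therefore not be run, and gene identity is not analysed here. Of the rule for named items, only its part for unnamed clones applied: the 2 clones that rose and the 2 that fell with the lowest p, among those whose groups did not overlap. The comparison of clones by the letter in their number was added after the data were seen.

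The alternatives were median centring, no scaling, z scores, cyclic loess, leaving out the dimmest 25% of clones, an offset at the 5th percentile of the intensities, a trended and robust variance, array weights, 2 other tests per clone, the run as a block or alone, and leaving out each array. Added after the data were seen were subtraction of each array's 1st percentile (values then under the 5th percentile of the positive ones were set to it), averaging of arrays with adjacent title numbers, these arrays as a random block (estimated correlation 0.77), and permutations of single array values restricted to the 36 orderings within runs, whose smallest p is 0.056.

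The fit was tested on simulated data: 20 sets of 1152 clones with the real means and spreads and 200 changed clones. With independent arrays it recovered 72.2% of the 1.5-fold, 90.9% of the 2-fold and 98.0% of the 3-fold changes, and 9.56% of its calls were unchanged clones. The share was 4.50% for simulated values that held no differences in array brightness and were not scaled. When adjacent arrays shared their deviations as strongly as in the data, 39.2% of its calls were unchanged clones. After averaging adjacent arrays this share was 6.86%, with a recovery of 31.3%, 73.7% and 91.7%. The simulation drew these deviations separately in each group, whereas in the data they correlated across groups within a run. It also changed far fewer clones than were called in the data. The simulated shares are therefore not error rates of the calls below.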

Results

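The supraoptic nucleus is a hypothalamic nucleus whose magnocellular neurons make vasopressin and oxytocin. RNA from this nucleus was compared between control rats and rats dehydrated for 3 days, with 4 arrays per group and 1152 spotted cDNA clones per array. Clone numbers run from 1 to 1152, and each carries the letter c or d, 576 clones with each letter. The sample descriptions call the array a "SON-C-D Clone array", but the labels do not explain the letters. They follow the numbering in stretches: d for 1 to 182, c for 183 to 200, d for 201 to 265, c for 266 to 823 and d for 824 to 1152. Which transcript a clone carries is not analysed here, so the clones are described by number, letter and brightness.

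Total intensity ranged from 4652440 to 9933170 on the control arrays and from 8333210 to 17278000 on the dehydrated arrays. After quantile normalization, arrays of a group with adjacent title numbers correlated at 0.995 across clones in all 4 cases, and arrays of a group from different runs at 0.963 to 0.968. Control and dehydrated arrays correlated at 0.802 to 0.843. The median gap between 2 arrays was 0.074 to 0.093 on the log2 scale for adjacent numbers, 0.22 to 0.25 for arrays of a group from different runs, and 0.58 to 0.70 between groups.

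The first comparison was of overall brightness before any scaling. The median log2 intensity was 11.38 ± 0.41 (SD, n = 4) on control arrays and 11.76 ± 0.29 (SD, n = 4) on dehydrated arrays. The difference of 0.39 was not larger than the spread between arrays of both runs together (exact permutation test, two-sided p = 0.20, adjusted p = 0.25 over 5 array measures). It was 0.49 within arrays 3 to 6 and 0.29 within arrays 16 to 19, and both dehydrated arrays were above both control arrays in each run (exact p = 0.056 over the 36 orderings within runs, the smallest they allow). The 10 brightest clones of an array held 7.07% ± 0.26 (SD, n = 4) of its signal on control arrays and 9.76% ± 0.27 (SD, n = 4) on dehydrated arrays, higher on 4 of 4 dehydrated arrays than on any control array (exact permutation p = 0.0286, the smallest this design allows, adjusted p = 0.048). Over the 36 orderings within runs the exact permutation p of this share was 0.056, the smallest they allow.

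The main question was which clones differ between dehydrated and control nuclei. Taking the 8 arrays as separate samples, 466 of 1152 clones were higher and 365 lower on dehydrated arrays, 72.1% of the array in all, and 321 did not pass the threshold (limma, Benjamini-Hochberg adjusted p under 0.05). Since the series title names SSH, the spotted clones may be preselected for such differences, and 72.1% is not a share of all transcripts. Averaging the arrays with adjacent title numbers, which may not be independent, left 517 called clones (44.9%), 262 higher and 255 lower, all among the 831. With these arrays as a random block, 649 were called, 357 higher and 292 lower. Changes of 2-fold or more were found for 251 of the 831 clones, 104 higher and 147 lower. Of these, 29 clones were lower by 4-fold or more and 1 was higher by that much. These 4-fold counts depend on the processing: they were 9 lower and 8 higher with no scaling, and 129 lower and 79 higher with each array's 1st percentile subtracted as background. That subtraction set low values to a floor, so the counts after it depend on the floor as well. The 4 dehydrated arrays did not overlap the 4 control arrays for 764 clones (66.3%). Chance gives 2.86% if the 8 arrays are independent, which the correlations of adjacent arrays argue against. Only 3 splits keep adjacent arrays together, so the share by chance would then be higher. Every called clone had the same sign in both runs of title numbers. The runs are parts of the 8 arrays that gave the calls, so this follows largely from the calls themselves. Arrays 3 to 6 alone called 938 clones and arrays 16 to 19 alone 926, and 834 clones passed with the same sign in each run. The error within 1 run is only the spread between arrays with adjacent title numbers, which may be technical. The split depends on the scaling: with no scaling between arrays, 569 clones were higher and 115 lower.

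The c clones and the d clones moved apart. Of the 576 c clones, 354 were lower and 33 higher on dehydrated arrays, and 189 did not pass. Of the 576 d clones, 433 were higher and 11 lower, and 132 did not pass. The median difference (dehydrated minus control) was -0.54 for c clones on the log2 scale, with the middle 50% from -1.0 to -0.076, and 0.61 for d clones, with the middle 50% from 0.34 to 0.88. All but 3 of the 147 clones that fell by 2-fold or more were c clones, and all but 2 of the 104 that rose by as much were d clones. With adjacent arrays averaged, 251 c clones were lower and 256 d clones higher, with 6 c clones and 4 d clones called the opposite way. The calls of the c clones depend on the scaling: with none, 115 c clones were lower and 79 higher, and 490 d clones were higher and 0 lower (limma; 1 at an unadjusted p under 0.05). Subtracting the 1st percentile moved the medians to -0.89 for c clones and 1.12 for d clones.

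**Figure D1:**
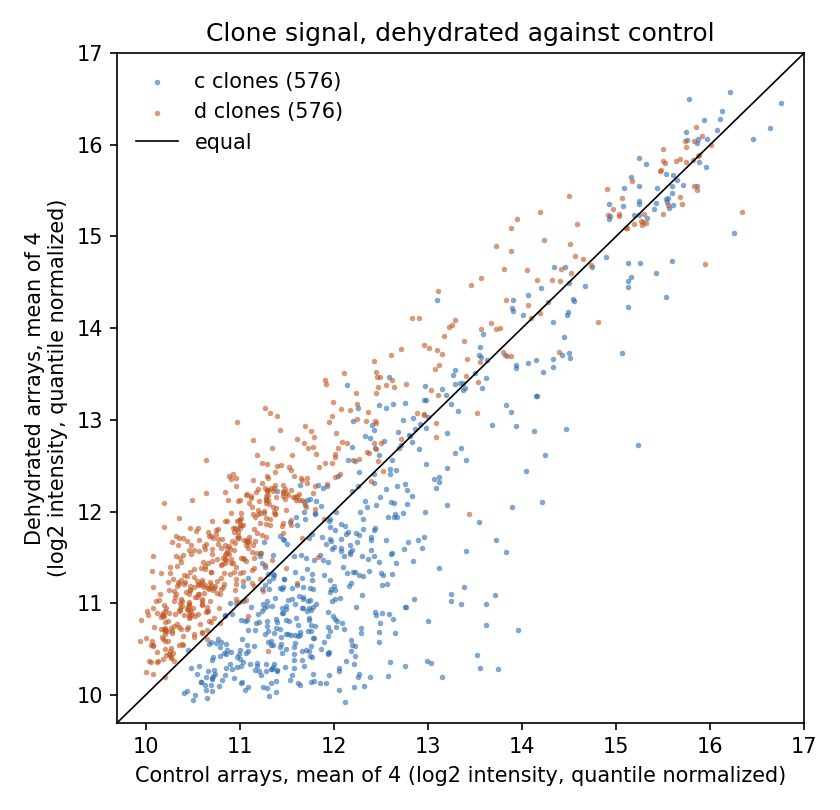
Mean log2 intensity of each clone on the 4 control arrays (x axis) against the 4 dehydrated arrays (y axis) after quantile normalization, 1 point per clone, c clones in blue and d clones in orange, with the line of equal signal. Most d clones lie above the line (433 called higher) and most c clones below it (354 called lower), and the brightest clones of both letters lie near it under this scaling.

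The gap between the letters can be read within each array, where a factor that scales the whole array cancels. On the control arrays the median d clone lay below the median c clone, with a d minus c gap of -1.28 to -0.88 on the log2 scale. On the dehydrated arrays it lay above, with a gap of 0.38 to 0.45. The gap averaged -1.08 ± 0.21 (SD, n = 4) in controls and 0.42 ± 0.032 (SD, n = 4) in dehydrated arrays, a difference of 1.5 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.048). Over orderings within runs its exact permutation p was 0.056, the smallest they allow. Within arrays 3 to 6 the difference was 1.32 and within arrays 16 to 19 it was 1.69. As deposited, the array median of the d clones rose by 1.14 (exact permutation p = 0.0286, adjusted p = 0.048, and exact p = 0.056 over orderings within runs). The change of -0.37 in the array median of the c clones was not larger than the spread between arrays of both runs together (exact permutation p = 0.29, adjusted p = 0.29). Those orderings mix the runs, so the difference between the runs enters this p. Within arrays 3 to 6 the c median changed by -0.20 and within arrays 16 to 19 by -0.53. Both dehydrated arrays were below both control arrays each time (exact permutation p = 0.056 over orderings within runs, the smallest possible). Taken clone by clone instead, the median of the clones' own differences also depends on the scaling: over all clones it was 0.17 after quantile normalization, 0.34 after median centring and 0.73 with no scaling, and over c clones -0.54, -0.45 and -0.065 in turn. The -0.065 is a median of differences and the -0.37 a difference of medians, both unscaled.

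**Figure D2:**
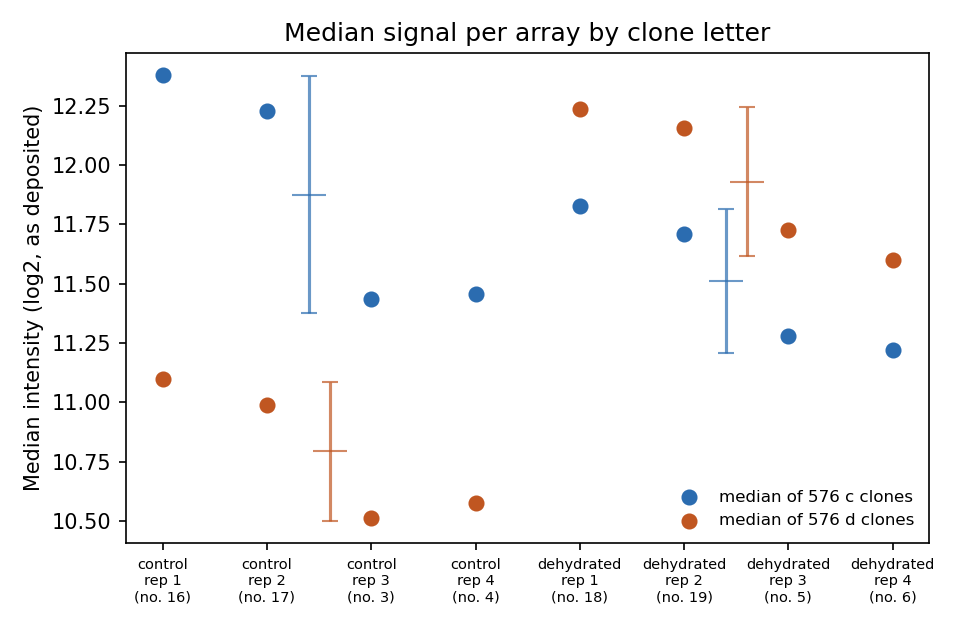
Median intensity (log2, as deposited) of the 576 c clones (blue) and the 576 d clones (orange) on each of the 8 arrays, with the mean and SD of each group of 4 arrays as bars and title numbers in parentheses. The c median is above the d median on all 4 control arrays and below it on all 4 dehydrated arrays.

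**Figure D3:**
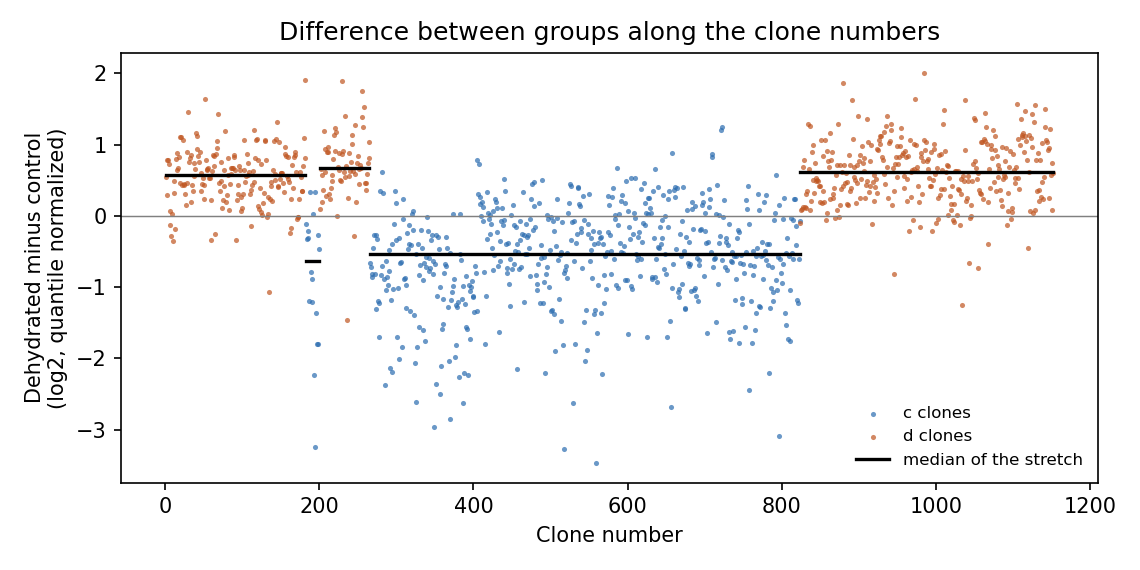
Difference between dehydrated and control arrays (log2, quantile normalized, y axis) of each clone against its clone number (x axis), c clones in blue and d clones in orange, with the median of each stretch of a letter as a black line. The medians are 0.57, 0.68 and 0.62 in the 3 stretches of d clones and -0.63 and -0.54 in the 2 stretches of c clones.

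The rule fixed beforehand named 4 clones, the 2 with the lowest p in each direction. Clone c517 fell from 13.56 ± 0.17 to 10.29 ± 0.076 (log2, SD, n = 4), 9.62-fold, and clone c796 fell from 13.52 ± 0.10 to 10.43 ± 0.13 (SD, n = 4), 8.51-fold. Their limma adjusted p was 6.1e-08. The deposited intensity of c517 ran from 5712 to 15070 on control arrays and from 1344 to 1514 on dehydrated arrays, near the lowest intensities of those arrays. Clone d984 rose from 10.97 ± 0.14 to 12.98 ± 0.063 (SD, n = 4), 4.03-fold, and clone d230 rose from 10.19 ± 0.11 to 12.09 ± 0.070 (SD, n = 4), 3.73-fold, with a limma adjusted p of 2.7e-07. With adjacent arrays averaged, the limma adjusted p was 0.0040 for d984 and 0.0042 for d230. The deposited intensity of d230 was 953 to 1013 on control arrays and 3635 to 6133 on dehydrated arrays, and its control values are also near the lowest of their arrays. The size of such changes depends on the scaling and on the treatment of the background. The log2 change of c517 was -3.27, against -2.66 with no scaling and -2.47 with the offset at the 5th percentile. That of c796 was -3.09, against -2.46 and -2.36, that of d984 2.01, against 2.41 and 1.56, and that of d230 1.90, against 2.27 and 1.26. With the 1st percentile subtracted, the change of d984 was 2.90. For the other 3 clones the subtraction left values that were set to a floor (on 2 arrays for c517, 1 for c796 and 3 for d230), so no size is given. The folds above are those of intensities with any background included. The log2 change of c517 was -3.06 in arrays 3 to 6 and -3.47 in arrays 16 to 19, and that of d984 was 2.03 and 1.99.

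The calls were also counted by brightness, as the mean over all 8 arrays. In the dimmest 25% of clones, 94 of 108 c clones were lower and none higher, and 147 of 180 d clones were higher and 1 lower. Above the 75th percentile and up to the 95th, 41 of 126 c clones were lower and 13 higher, and 54 of 104 d clones were higher and 6 lower. Among the brightest 5%, 58 clones, 43 did not pass. Of its 35 c clones, 7 were higher and 3 lower, and of its 23 d clones, 2 were higher and 3 lower. After quantile normalization the median difference of d clones was 0.51 in the dimmest 25%, 0.73 and 0.78 in the next 2 bands, 0.45 up to the 95th percentile and 0.16 in the brightest 5%. This order turns with the scaling: the brightest d clones had the highest of the 5 medians with median centring (1.02, against 0.56 in the dimmest 25%) and with no scaling (1.41 against 0.95). With the 1st percentile subtracted the medians fell from 1.39 in the dimmest 25% through 1.31, 1.14 and 0.49 to 0.16 in the brightest 5%. Low values were then set to a floor, so the size in the dimmest clones depends on that floor. Over both letters the brightest 5% had a median difference of 0.075 after quantile normalization, 0.95 after median centring and 1.34 with no scaling. The 0.075 also depends on single arrays: it was 0.021 without control replicate 1 and 0.10 without control replicate 3.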

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

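The tests of array brightness and of a shared factor were chosen only after the result was seen, and so were the counts of splits within runs and of splits that keep adjacent arrays together. The test at the letter changes and the count of all splits were written before theirs.

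The d minus c gap was singled out because it differed between control and dehydrated arrays by 1.5 on the log2 scale. A difference in array brightness or scaling is argued against by the 2 dehydrated arrays of run 3 to 6: they are dimmer than the 2 control arrays of run 16 to 19 (median lower by 0.21), yet their gap is higher by 1.67. A smooth trend along the clone numbering is argued against by the steps at the 4 places where the letter changes, which were 0.85 to 1.44 between the 18 clones on either side; the smallest, 0.85, had a 95% bootstrap interval of 0.40 to 1.32. A single factor shared by all clones of a letter is argued against as the whole cause, since it would shift bright and dim clones alike: unscaled, the median change of d clones exceeded that of c clones by 1.09 to 1.5 in the 3 dimmest brightness bands and by 0.15 among the brightest 5% (95% bootstrap interval -0.15 to 0.36). A factor that acts on dim clones more than on bright ones and differs between control and dehydrated arrays stays open. An effect on signal of how the clones of each letter were prepared or printed would be one only if it differed between these arrays. A factor on a clone's signal that all arrays share cancels in the difference between groups. The choice of transcripts for each letter is not such a factor. A choice by subtraction could give the pattern with the same clones on every array, and it also stays open. The dehydration itself may account for the pattern and remains a hypothesis.

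The count of 831 called clones was set against the 35 splits of the 8 arrays into 4 and 4. Only 1 split, the real one, gave as many, but this count takes the 8 arrays as independent, which their correlations argue against. The highest other split, with 40 clones, was the one that follows the runs of title numbers; with the run as a block, 982 clones were called. Of the 18 splits with 2 arrays of each run in each part, the real one gave 831 clones and the highest other 0. Of the 3 splits that keep adjacent arrays together, the real one gave 831 and the highest other 40. Both sets are too few for a share under 0.05. Every split other than the real one also mixes control and dehydrated arrays in each part. The difference between the groups then adds to the error and lowers the count, so these counts are not those expected by chance.

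The difference between dehydrated and control arrays itself differed between the 2 runs for 90 of 1152 clones (limma interaction term, adjusted p under 0.05). The count was 291 after median centring, 183 with no scaling and 27 after subtraction of the 1st percentile. The error in this fit is only the spread between arrays with adjacent title numbers, which may be technical, so these counts do not show that the response of the animals differed between the runs.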

How the results depend on the processing

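The number of calls, 831, stayed within 1.5 times under 23 of 24 alternatives (lowest 517, highest 982). The clones called were not always the same. With no scaling, 554 of the 684 called clones were among the 831, and with median centring 735 of 817. Clones c517, c796, d984 and d230 kept their direction and passed in all 24 (highest adjusted p 0.043, from the exact permutation test per clone). Leaving out each array gave 792 to 812 calls. The larger moves were as follows. Averaging arrays with adjacent title numbers gave 517 calls, 262 higher, with 256 d clones higher. With no scaling, 115 clones, all of them c clones, were lower. Without the dimmest 25%, 283 d clones were higher, since fewer clones were tested. The median c clone (-0.54) moved to -0.45 with median centring, -0.065 with no scaling, -0.60 with cyclic loess, -0.50 without the dimmest 25%, -0.37 with the offset, -0.58 in run 3 to 6, -0.50 in run 16 to 19 and -0.89 with the background subtracted, and lay between -0.55 and -0.52 when each array was left out. The median d clone (0.61) moved to 0.68, 1.07, 0.54, 0.67 and 0.42 under the first 5 of these and to 1.12 with the background subtracted. No median changed sign. Apart from the number of clones tested, the cause of these moves was not tested. The 33 c clones called higher ranged from 6 (adjacent arrays averaged) to 79 (no scaling), and the 11 d clones called lower from 0 (no scaling) to 20 (run 16 to 19). The gap and the brightness shift kept their direction under all 13 of their alternatives. Without each array in turn, the gap difference was 1.44 to 1.57 with an exact permutation p of 0.0286 each time; within a single run, or with orderings within runs (p = 0.056), the design is too small for a p under 0.05. The labels give the groups no shared replicate numbers, so arrays were not paired one by one; the block used was the run. The alternatives listed beforehand for genes and gene lists were not run, since the clones are not paired with genes here. Signal close to the array's lowest values limits the size of any fall.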

Other observations

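The tests in this part were chosen after the pattern was seen, except the comparison of pairs within and across plates.

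The clones that went against their letter were brighter, by their medians, than those that went with it. So were the clones that did not pass, so this is not particular to clones that went against their letter. The 189 c clones that did not pass had a median control intensity of 5637 and a median dehydrated intensity of 7931. For the 132 d clones that did not pass these were 5011 and 7891. The 33 c clones called higher had a median control intensity of 4551 and a median dehydrated intensity of 10154, while the 354 c clones called lower had 3560 and 2097. The 11 d clones called lower had medians of 16883 and 18411, and their number depends on the scaling: 3 d clones were called lower with median centring and 0 with no scaling. The 433 d clones called higher had medians of 1628 and 3824. The largest rise of a c clone was 1.24 and the largest fall of a d clone -1.46 on the log2 scale. The short stretch of 18 c clones between d clones (183 to 200) had a median difference of -0.63, close to the -0.54 of the 558 c clones from 266 to 823. The 3 stretches of d clones had medians of 0.57, 0.68 and 0.62.

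One hypothesis is that c and d name clones from libraries subtracted in opposite directions, control-enriched and dehydration-enriched. It needs most called c clones to be lower and most called d clones to be higher on dehydrated arrays. This held for 91.5% of the called c clones and 97.5% of the called d clones after quantile normalization. With no scaling it held for only 59.3% of the called c clones and for 100% of the called d clones. That setting leaves differences in array brightness in the calls. Under the other alternatives it held for 82.5% (median centring) to 97.7% (adjacent arrays averaged) of the called c clones. The share thus depends on the scaling, and the hypothesis stays open. The array name, SON-C-D, holds the same letters, but the labels do not say what they stand for. The letters were read this way only after these values were seen, and a library enriched for a difference would not be independent evidence of that difference in these animals.

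Clones with neighbouring numbers changed alike. Only each letter's median was removed before this comparison, while the differences also varied with brightness. The median c clone was at -0.82 in the second dimmest band and at 0.066 in the brightest 5%. Likeness that goes with brightness is therefore not separated from the correlations. With each letter's median removed, the log2 differences of clones 1 apart in a row of an assumed 96-well plate with 12 columns correlated at 0.22 over 1052 pairs (permutation p = 1e-04, the smallest 10000 permutations can give, adjusted p = 0.00018 over 7 kinds of pair), and clones 12 apart in a plate at 0.29 over 966 pairs (the same p). A slow trend over the array stays open: clones 3 apart correlated only 0.36 times as strongly as clones 1 apart, but clones 2 apart correlated at 0.22, and clones 24 apart in a plate at 0.20. Signal or DNA shared between neighbouring wells or spots may also account for it and cannot be told apart from such a trend: pairs 12 apart correlated more within a plate than across plates by 0.15 (one-sided permutation p = 0.071), and pairs 1 apart correlated less within a row than across rows, by -0.11 (p = 0.83). The plate layout was assumed from the clone number and is not given in the sources used here.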
